A study of Mus musculus with 2 samples.

How the data were processed

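Chromatin from sorted Clec3b-reporter portal fibroblasts of mouse liver with lentiviral Klf4 was cross-linked, sonicated and precipitated with an antibody against KLF4, per the labels' protocols. There were 2 libraries, 1 KLF4 ChIP and 1 input, and the groups were taken from the sample titles. The labels' protocol also names a control immunoglobulin precipitation, which was not analysed here. The submitters' processing notes name bcl2fastq 2.17, fastp 0.24.0, Bowtie2 2.4.2, deepTools 3.4.1, MACS2 2.2.7.1 and ChIPseeker 1.44.0, and the build GRCm39 (mm39). Their settings are not given in the sources used here.

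The deposited table is a single annotated peak list of the ChIP library against the input. The fold enrichment of each peak is the authors' linear ratio of ChIP over local background, with 1 added to each. The deposited −log10 columns are those of the p-value and q-value of each peak, and the authors also gave each p-value and q-value directly. Annotation class, nearest gene, transcript and distance to the TSS were used as deposited, with promoters reaching 3 kb from the TSS. The peak names ran to 4239 for 4216 peaks, and the 23 numbers in between were not analysed here. Read totals of the libraries were not used here, and absolute depth was not estimated.

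The number of ChIP fragments at each summit (the height) and the background were recovered from fold and p. MACS2 writes fold as height plus 1 over background plus 1, and p as the Poisson chance of exceeding the height given the background. A whole-number height fitted all 4216 peaks within 0.001 of the deposited −log10 p. On 1000 simulated peaks all heights (100%) were recovered, and of 1000 simulated peaks with heights that were not whole 0.7% were fitted that closely. The lowest background, 0.307 fragments, was read as the genome-wide one. A background of 0.542, seen at 723 peaks, was read as 1 input fragment scaled to the ChIP library, which puts ChIP depth at 54.2% of input depth. Other backgrounds came from wider input windows of 1 kb and 10 kb, and the step of the 10 kb windows corresponds to a fragment length of 84.6 bp. That is shorter than the 100 to 500 bp of sonicated chromatin in the labels' protocols, a difference left unresolved because the peak caller's settings are not given in the sources used here. The length was derived by taking the steps as 10 kb windows, and heights and backgrounds were recovered without it. Background over 10 times the genome-wide one was called high, a limit set after the data were seen. Such peaks with gaps of at most 500 kb were joined into blocks of at least 5 peaks, and blocks over 100 kb were called broad.

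Shares have 95% exact (Clopper-Pearson) intervals, which cover counting error only. Promoter and other peaks were compared by a two-sided permutation test of the difference in median fold with 100000 resamples. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 20 lists and a threshold of 0.05. The peak list's gene symbols were matched to a gene table of the older assembly GRCm38.p6, used only for names and for counting genes. Of 1585 protein-coding symbols, 1506 (95.0%) matched, and 38 of the 79 unmatched were olfactory receptor symbols. On 200 simulated lists of 20 genes with no effect, 2 had an unadjusted p under 0.05. Distances to the TSS are given as counts without a test. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with fixed random seeds.

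Tests, gene lists and the rule for named genes were fixed before the data were examined. That rule took Klf4, Postn and Clec3b, the 10 genes with the strongest promoter peaks and the 10 with the strongest other peaks by fold (1 peak per gene, leaving out the mitochondrial genome and unplaced contigs), up to 4 members per list with the strongest peaks, and the 5 genes with the most peaks. The same results were also computed with a q limit of 1e-05, nuclear chromosomes only, peaks above the median fold, a promoter limit of 1 kb, other measures of strength, any assigned peak, and 10000 random lists matched on gene length. Tests of KLF motifs, random placement of peaks, promoters by another annotation and matching on CpG content need a genome, and none was used here. Some named genes and positions are not reported here.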

Results

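The data described the binding of KLF4, a zinc-finger transcription factor, in portal fibroblasts, the matrix-producing cells around the portal tracts of the liver. The cells were sorted from mouse livers by a red reporter driven from Clec3b, a gene for a secreted plasminogen-binding protein, and carried extra Klf4 delivered by lentivirus. The study asked how KLF4 acts on the change of these cells into myofibroblasts, the contractile cells of scar tissue, and its title names periostin. Chromatin immunoprecipitation with sequencing (ChIP-seq) was represented by 1 KLF4 ChIP library and 1 input library, so no value below has a replicate error. The fold enrichments, p-values and q-values of peaks are the authors' own. Every test across peaks or genes describes this list of peaks and not a difference between cell populations. Positions are on GRCm39.

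The list held 4216 peaks, assigned to 3648 nearest genes. Most were short and shallow. Median width was 201 bp (quartiles 142 and 293 bp) and median fold enrichment over input was 4.59 (quartiles 4.54 and 4.94, range 1.62 to 14.5). The number of ChIP fragments over each summit, recovered from the fold and p of the peak, was 5 at 1633 peaks and 6 at 1543 peaks. Together these made up 75.3% of the list (95% exact binomial interval 74.0% to 76.6%, which covers counting error only). Only 275 peaks had 10 or more fragments, and 73 of these lay where the background was at most 10 times the genome-wide background. The genome-wide background was 0.307 fragments, and 1172 peaks (27.8%) sat at that level. The highest q in the list was 0.0491, 735 peaks (17.4%) had a q under 0.01, and 115 had a q under 1e-05.

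**Figure D1:**
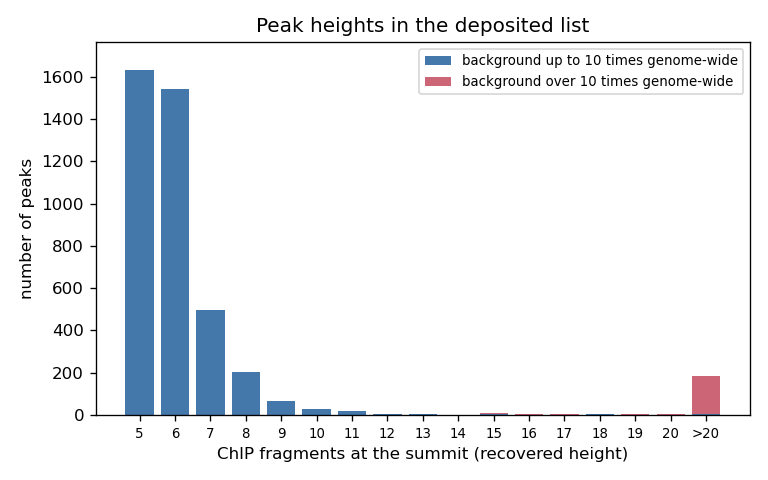
Number of peaks (vertical axis) by the number of ChIP fragments over the summit (horizontal axis, the last bar holding all heights over 20), split by whether the input-derived background was over 10 times the genome-wide one. The bars at 5 and 6 fragments hold 3176 of the 4216 peaks.

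Periostin, the matricellular protein named in the study's title, had 1 peak. It covered 185 bp of chromosome 3, from 54294950 to 54295134, and was annotated as promoter at 1 to 2 kb. The distance was -1176 bp (upstream) from the start of a Postn transcript that ran only from 54296310 to 54297814. Whether this short transcript starts at the main Postn promoter was not checked. The fold enrichment of the peak was 4.54, from 6 ChIP fragments against a background worth 1 input fragment, with a q of 0.0484. In the list, 3167 peaks had a lower q, 1049 peaks (24.9%) had the same q or a higher one, and 563 peaks had exactly its fold and q. Among the 868 promoter peaks, 660 had a lower q. The peak was not among those with a q under 1e-05, with a fold above the median or within 1 kb of a transcription start site (TSS), where the number of Postn promoter peaks was 0. No peak was assigned to Klf4 itself or to Clec3b (0 peaks each), which at this depth does not show that binding was absent.

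By genomic annotation, 868 peaks (20.6%, 95% exact interval 19.4% to 21.8%) were within 3 kb of a TSS. Distal intergenic peaks made up 43.1% (1815 peaks, 41.5% to 44.6%) and intronic peaks 32.0% (1349 peaks, 30.6% to 33.4%). Exons held 63 peaks, 3′ untranslated regions 66, 5′ untranslated regions 2 and the stretch just downstream of genes 53. The nearest gene was protein-coding for 1856 peaks (44.0%), a long non-coding RNA for 856 and a processed pseudogene for 788. With promoters taken as up to 1 kb from the TSS, the promoter share was 10.1%.

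By distance, 425 peaks lay up to 1 kb from the nearest TSS and 241 at 1 to 2 kb, so that 63.8% of these fell in the nearer band (95% exact interval 60.0% to 67.5%). Peaks of protein-coding genes numbered 283 and 143 in these bands, and peaks of other genes 142 and 98. Peaks of only 5 or 6 fragments numbered 313 and 179. These are values without a test, since distances were taken to the nearest TSS and random placements of the peaks were not run. They were chosen after the distances had been seen.

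The median fold was 4.59 for the 868 promoter peaks and 4.59 for the 3348 other peaks, a difference of 0 (permutation test, two-sided, p = 1). Medians of fold, −log10 q and height were tied because most peaks shared a few fragment numbers, so this test, fixed in advance, could not show whether promoter peaks differed in strength. The mean folds were 4.74 and 4.72 (permutation p = 0.621). Without peaks in high background the means were 4.85 and 4.80 (permutation p = 0.0104, adjusted permutation p = 0.0209 over the 2 tests of means and 0.0731 over all 7 settings, of which 5 were tied). The means were added after the data had been seen.

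Among promoter peaks, the highest fold, 9.90, belonged to the processed pseudogene Gm8357. Hdgfl2, which encodes a chromatin-binding protein of the HDGF family, followed at 9.71, with a peak of 645 bp spanning its TSS on chromosome 17 (56386036 to 56386680) and 12 ChIP fragments. The non-coding gene Gm55523 had a fold of 9.60 over 3205 bp of chromosome 19, the widest peak in the list. The pseudogene Gm15602 had 9.19 and S100a14, a calcium-binding protein gene, 9.03. The others were the pseudogene Vmn2r-ps34 (7.15), the histone gene H2ac13 (7.13), the annexin gene Anxa7 (7.08), the ubiquitin ligase gene Rnf181 (7.08) and the transporter gene Slc16a11 (6.89).

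Away from promoters, the strongest peak of the list lay near the pseudogene Gm7241 on chromosome 1 (132215689 to 132216342), with a fold of 14.5 and 18 ChIP fragments. Next came an intronic peak assigned to the pseudogene Gm13197 (12.2) and an intronic peak of Frs2, an adaptor of fibroblast growth factor receptors, on chromosome 10 (116958779 to 116958898, fold 11.8). The rest were assigned to Gm15232 (9.20), Gm57076 (8.41), Mir101c (8.38), Gm19276 (7.78), Gm24036 (7.65), Gm14443 (7.65) and Gm55757 (7.60). The Frs2 peak, at 2.00 times the genome-wide background, lay just before a stretch of high input background that began at 116987721. The Mir101c peak, at 5.29 times, lay inside a stretch of chromosome 9 with high input background (2999999 to 3038262). The genes with the most peaks were Mir101c, with 25 peaks at the start of chromosome 9 (median input background 12.3 times the genome-wide one), and a protein-coding gene without a symbol (ENSMUSG00000095041), with 17 on the unplaced contig JH584304.1 (10.6 times). Gm32235 had 16, the nuclear pore gene Nup107 13 and the carboxypeptidase gene Cpm 12, all on chromosome 10 where the median input background was 57.3, 59.9 and 56.3 times the genome-wide one.

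For the change into myofibroblasts, 20 gene lists fixed before the data were examined were compared with all protein-coding genes of the gene table, of which 479 of 21887 (2.19%) had a promoter peak under a matching symbol. Olfactory receptor genes, whose symbols did not match, count in that share as genes without a peak; without them it was 2.31% (479 of 20777), and 0 lists passed. No list passed Fisher's exact test after Benjamini-Hochberg adjustment (0 of 20), and 1 had an unadjusted p under 0.05. That list was the myofibroblast and contractile genes, with promoter peaks at 3 of 20 members (15.0%, 95% exact interval 3.21% to 37.9%; Fisher's exact p = 0.0090, adjusted p = 0.180). The 3 were Cald1, the actin-binding caldesmon (fold 5.62, 9 fragments), Vim, the intermediate filament vimentin (5.04, 7 fragments), and Myh9, a non-muscle myosin heavy chain (4.59, 5 fragments). Fap and Mylk had intronic peaks only. With promoters limited to 1 kb, the same 15.0% of the list had a peak and the list passed (Fisher's exact, adjusted p = 0.0340, or 0.0394 without olfactory receptor genes, a setting added after the data had been seen). That adjustment covered the 20 lists of this setting, not all 140 list comparisons under alternatives. The Cald1 peak within 1 kb was a weaker one (fold 4.97, 7 fragments). Against random lists matched on gene length, with promoters up to 3 kb, the adjusted p was 0.520.

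The extracellular matrix list had a promoter peak at 1 of 26 genes, Postn, while Loxl1, Bgn and Fbn1 had peaks elsewhere (Fisher's exact, adjusted p = 0.729). Postn counted through the start of the short transcript at 54296310, which was not checked against the main start of the gene. Among TGF-β and BMP signalling genes, 2 of 28 had one (adjusted p = 0.498, Fisher's exact), namely the transcriptional regulators Id1 (fold 4.59) and Tgif1 (4.48), and the inhibitory Smad6 and the ubiquitin ligase Smurf1 had intronic peaks. Other lists each had 1 gene with a promoter peak: Itgb5 of 20 integrin and adhesion genes, Klf3 of 21 KLF and SP family genes, Ier2 of 20 immediate early genes, Nf2 of 16 Hippo genes and Ccl2 of 20 inflammatory genes. Ier2 had a fold of 6.65 and Ccl2, a monocyte chemoattractant, 6.23, each from 8 fragments. In the housekeeping list, the glycolytic gene Gapdh had a promoter peak with a fold of 5.35. None of these lists passed the adjusted Fisher's exact test.

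Marker lists of fibroblasts had no promoter peaks, with 0 of 23 portal fibroblast markers (upper limit of the exact interval 14.8%) and 0 of 20 hepatic stellate cell markers (16.8%). The matrix turnover list also had 0 of 20, with Adamts1, Adamts5 and Adamts12 bearing peaks elsewhere. The Wnt, Hedgehog and Notch list had 0 of 21, with peaks elsewhere at Notch2, Tcf7l2 and Jag1. The pluripotency, cholangiocyte, hepatocyte and endothelial lists each had 0 of 14, with peaks elsewhere at Zfp42, Epcam and Stab2. Among macrophage and leukocyte markers the lysozyme gene Lyz2 was 1 of 14, and among cell cycle genes the replication gene Mcm5 and the p53 regulator Mdm2 were 2 of 21. The peaks of Lyz2 and Mdm2 lay on chromosome 10 in high input background, with folds of 3.45 for Lyz2 and at most 3.11 for Mdm2. Lists of 20 genes are small: in simulated lists with 5 times the background share, 70 of 200 reached an unadjusted p under 0.05, so enrichment of that size was often not detectable.

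**Figure D2:**
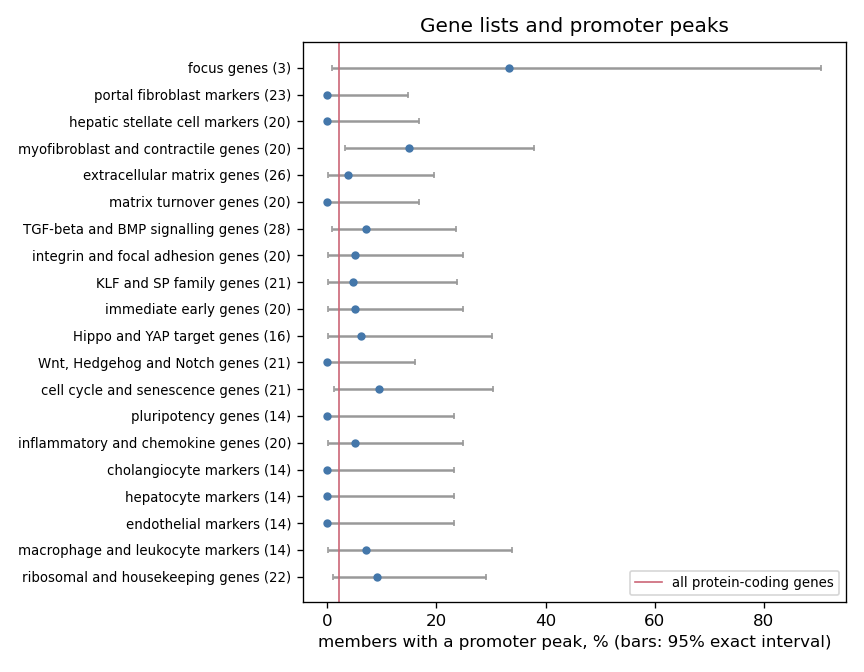
Percent of each fixed gene list with a promoter peak (horizontal axis), with bars for the 95% exact binomial interval and the number of members in brackets after each name on the vertical axis. The vertical line marks all protein-coding genes of the gene table at 2.19%, counted by matching symbol, and the myofibroblast list stands at 15.0%.

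The smallest q-values fell where the input itself was high. Input-derived background exceeded 10 times the genome-wide level at 202 peaks (4.79%). These made up 77 of the 115 peaks with a q under 1e-05 (67.0%) and 43 of the 50 peaks with the lowest q. Their median fold was 2.69, against 4.59 for the remaining peaks, and 38.1% of them had a q under 1e-05, against 0.947% of the rest. A high fragment number lets a lower fold reach the same p, so the median folds were compared as values without a test. The 1 added to ChIP and background in each fold also lowers it more where the background is low.

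**Figure D3:**
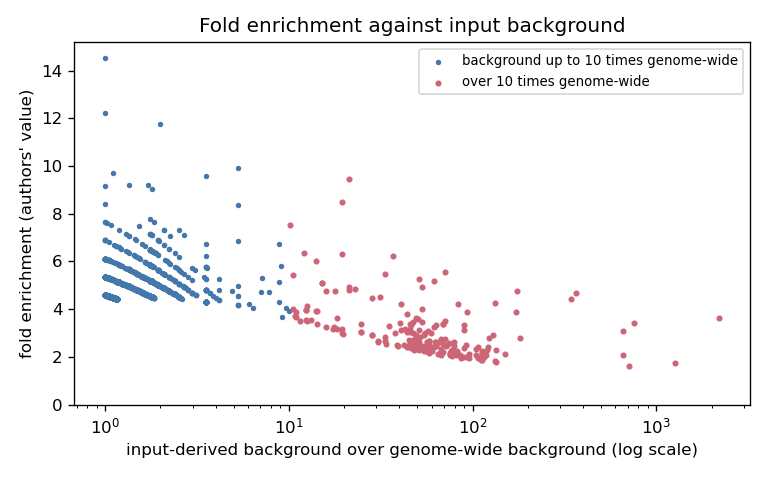
Fold enrichment of each peak (vertical axis, the authors' value) against its input-derived background divided by the genome-wide background (horizontal axis, log scale), 1 point per peak. The 202 peaks beyond 10 times the genome-wide background have a median fold of 2.69, and the others 4.59.

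The 202 high-background peaks were clustered. Of these, 37 lay in 4 stretches under 100 kb and 151 in 4 broad stretches of over 100 kb on chromosomes 1, 2 and 10. Among these 4 broad stretches the densest, on chromosome 10 from 116987721 to 117626313, held 109 peaks, or 171 per Mb against 1.56 per Mb over the nuclear chromosomes. Its median fold was 2.45.

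**Figure D4:**
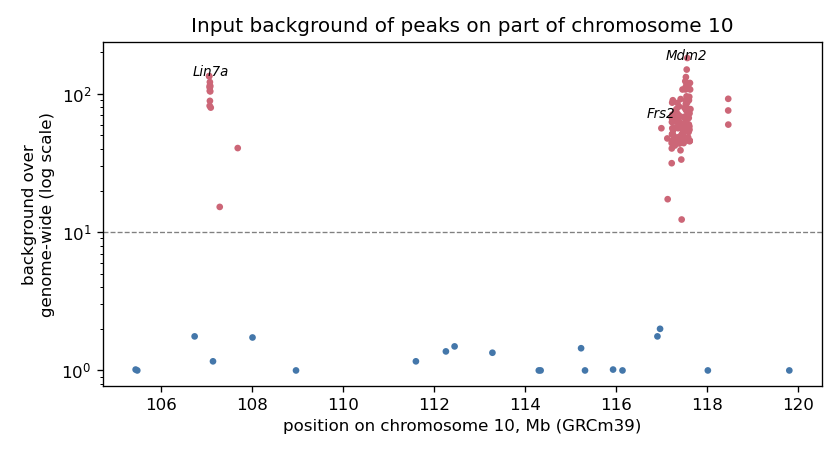
Input-derived background of each peak divided by the genome-wide background (vertical axis, log scale) by position on chromosome 10 in Mb (horizontal axis, GRCm39), with points over 10 times (dashed line) in red. The stretch with Frs2 and Mdm2 holds 109 peaks with a median of 58.2 times, and the high-background peaks of the stretch on the left have a median of 108 times, with a Lin7a peak inside it at 1.16 times.

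**Figure D5:**
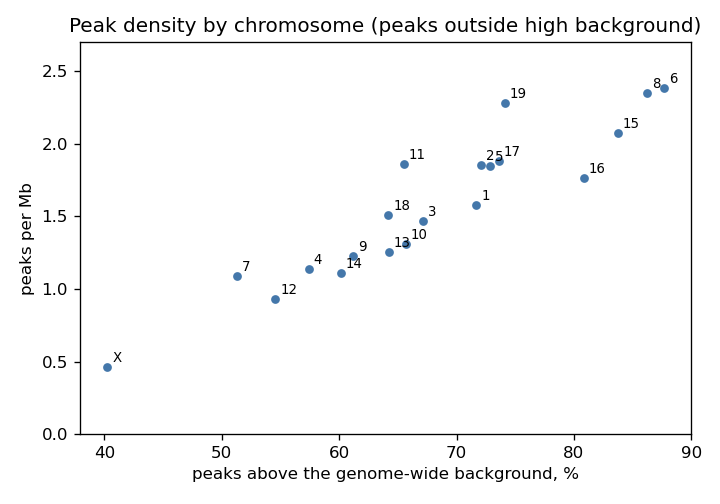
Peaks per Mb outside high background (vertical axis) against the percent of those peaks above the genome-wide background (horizontal axis), 1 point per chromosome (19 autosomes and X). Chromosome 6 stands at 2.39 peaks per Mb and 87.6%, and X at 0.464 and 40.3%. Both axes were counted from the same peaks, so they can rise together by construction.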

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

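All tests in this part were chosen after the values had been seen. In 4 broad stretches the input-derived background of peaks stood far above the genome-wide one, a signal of the input library that the comparisons of annotation and gene lists did not use. On chromosome 10 from 116987721 to 117626313, 109 peaks had a median background 58.2 times the genome-wide one, around Frs2, Lyz2, Cpm, Mdm2 and Nup107. A further stretch of chromosome 10 (107052181 to 107681096, near Lin7a and Otogl) stood at 108 times, a stretch of chromosome 1 near Esrrg at 15.9 times, and chromosome 2 from 77726979 to 77852589 (Cwc22) at 33.9 times. These medians are over the high-background peaks that define each stretch, 14 of the 15 peaks in the further stretch of chromosome 10 and 17 of 18 on chromosome 1. The genes were named after their values were seen.

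Extra copies of a stretch in the cells' DNA, relative to the reference, may raise the input; a gain of the whole further stretch of chromosome 10 was argued against by a Lin7a peak inside it at 107137215, whose background was 1.16 times the genome-wide one, and gains of parts of it stay open. For the other stretches the lowest background inside (12.3 times around Mdm2, 24.7 on chromosome 2 and 9.61 on chromosome 1) decides nothing, since all of their peaks but 1 were chosen for high background, and extra copies stay open there. Around Mdm2, 64.1% of the 10 kb tiles (41 of 64, exact interval 51.1% to 75.7%) held a high-background peak. This argues against high input at only a few single positions there. The stretch was built from such peaks, and many separate short repeats would fill tiles too, so short repeats stay open. At 61.5% on chromosome 2, 17.2% on chromosome 1 and 9.52% on the other stretch of chromosome 10, short repeats cannot be told apart from extra copies. Tiles without a peak show no input level. Input averaged over 10 kb reached a median of 32.3, 11.6 and 81.9 times the genome-wide background at 2, 5 and 3 peaks there. Such averages do not decide about short repeats, alone or several in a window, since input away from the listed peaks was not seen. Elsewhere on chromosome 2, a stretch of only 4.77 kb had a median background 756 times the genome-wide one. Gains of Mdm2, which restrains p53, occur in transformed cells and Cwc22 lies in a segment known to vary between mouse strains, but neither a gain in culture nor a strain variant was tested, and no biological explanation from the design was, as both libraries came from cells with the same treatment.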

How the results depend on the processing

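Tests without high-background peaks, of means, of the background without olfactory receptor genes, of TSS distance and of the Postn peak were chosen after the data had been seen; the others were planned. With a q under 1e-05, 115 peaks were left, of which 77 lay in high background. The median width of the 115 was 238 bp, the promoter share was 22.6% and the distal intergenic share rose to 59.1% from 43.1%. These values therefore describe mostly peaks in high input background. With promoters within 1 kb the promoter share of all peaks was 10.1%. The count on nuclear chromosomes, and the promoter share above the median fold or without high-background peaks, stayed close to the reported values. The difference between promoter and other peaks was 0 for medians of fold, −log10 q and height, which ties fixed; for the mean without high-background peaks it was 0.0551 (permutation p = 0.0104). Of the 20 lists, 0 passed in each setting except promoters within 1 kb, where 1 did. The ratio of peaks up to 1 kb to those at 1 to 2 kb was 1.45 for genes other than protein-coding ones, against 1.76 overall. Postn kept 0 promoter peaks at a q under 1e-05, above the median fold and within 1 kb, and 1 without high-background peaks. Shares of lists that crossed the background share, with 31 such changes among 140 and none with an adjusted p under 0.05, follow. Counting any assigned peak, the background share was 6.88%. Above it were matrix turnover at 15.0% and Wnt, Hedgehog and Notch at 14.3%. Pluripotency, cholangiocyte and endothelial, at 7.14% each (1 of 14), were barely above it. Hippo at 6.25%, integrin at 5.00% and KLF and SP at 4.76% were below it. Promoters within 1 kb gave 0% for the focus, matrix, integrin, Hippo and inflammatory lists. A q under 1e-05 gave 0% for the focus, myofibroblast, matrix, TGF-β, integrin, KLF and SP, immediate early, Hippo, inflammatory and housekeeping lists. Peaks above the median fold gave 0% for the focus, matrix, TGF-β, integrin, Hippo, cell cycle and macrophage lists, and leaving out high-background peaks gave 0% for the macrophage list. Where fewer peaks entered, as under the stricter limits, most lists had no peak left to count; other causes were not tested. KLF motif tests, random placement, promoters by another annotation and CpG matching were not run. No paired analysis was possible because each group had 1 library. Most peaks rest on 5 or 6 fragments, which limits every share and rank above.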

Other observations

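All tests in this part were chosen after the values had been seen. Taken as a whole, genes on the fixed lists had promoter peaks more often than other coding genes, at 16 of 363 (4.41%, exact interval 2.54% to 7.06%) against 2.27% of the other coding genes, leaving out olfactory receptor genes, whose symbols did not match (Fisher's exact p = 0.0124). Without high-background peaks 14 had one (Fisher's exact p = 0.0478), and within 1 kb 10 had one (Fisher's exact p = 0.0274). Outside high background, the tallest of their promoter peaks had 9 fragments. Gene length was not allowed for in these 3 tests. Of the 79 coding symbols that did not match, 38 were olfactory receptor symbols. Genes behind the rest could count only as genes without a peak, which may lower the share of the other coding genes.

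Olfactory receptor genes, which are silent in most tissues, had fewer peaks. A promoter peak was present at 13 of 1110 (1.17%, exact interval 0.625% to 1.99%) against 2.31% of other coding genes (Fisher's exact p = 0.0121). Other peaks only were present at 2.25% against 4.94% (Fisher's exact p = 9.9e-06). These peaks were assigned to the nearest gene, and the length of sequence from which each gene can collect peaks was not allowed for. The difference therefore cannot show a deficit over whole regions. Reads shared between paralogs, base composition and closed chromatin were not separated either. A specific preference of promoter peaks for open chromatin cannot be told apart from fewer peaks of any kind, since among genes with any peak the promoter share was 34.2% and 31.8% (Fisher's exact p = 0.728). Within 1 kb of the TSS the deficit was larger, at 0.270% against 1.27% of genes (Fisher's exact p = 0.0010), but among genes with any peak the shares of 7.89% and 17.5% rested on 3 olfactory receptor genes and did not pass (Fisher's exact p = 0.189).

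Peaks per Mb outside high background differed between the 19 autosomes and X, from 0.464 on X to 2.39 on chromosome 6 and 2.35 on chromosome 8; Y, with 2 peaks, was left out. Across these chromosomes the density rose with the share of peaks above the genome-wide input background (Pearson's r = 0.929, Spearman's rho = 0.931, permutation p = 1e-05 for each, the smallest these could give; adjusted permutation p = 3e-05 over 3 relations), and without the 2 chromosomes farthest from the median share r was 0.883. Both measures were counted from the same peaks, and peaks above that background add to the density as well as to the share. The density and the share can therefore rise together by construction, which the permutation p does not allow for. The relation thus decides nothing about its cause. Chromosome copy number, or another bias present in both libraries, stays possible, and the data do not separate these. Density of coding genes had r = 0.263 and rho = 0.362 (permutation p = 0.263 and 0.116, adjusted 0.263 and 0.122), and without the 2 chromosomes farthest from its median r was 0.482 (permutation p = 0.0423), so a contribution of gene density cannot be told apart from chance at this number of chromosomes. The promoter share of peaks had r = 0.394 and rho = 0.358 (permutation p = 0.0860 and 0.122, adjusted 0.129 and 0.122), and r was 0.134 without the 2 farthest chromosomes.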
